A study of Mus musculus with 6 samples.

How the data were processed

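RNA was measured by bulk RNA sequencing in 6 libraries from mouse liver. Per the labels, 3 libraries came from mice with floxed Ncor1 alleles and 3 from mice in which hepatocytes lacked NcoR1 (NcoR1ΔHep). Per the labels' protocols, total RNA was extracted with a Qiagen column kit and libraries were made with a SMARTer mRNA kit. The sample titles give 0 h of ischemia-reperfusion, while the treatment label of every library names liver ischemia-reperfusion. The labels do not say whether the 0 h livers underwent surgery.

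The deposited count table holds whole-number read counts per gene symbol, with 1 column per library and no normalization. The deposited FPKM table holds the same genes in the same libraries. Each FPKM value was a count scaled by a gene length and by the total of that library's counts. Among the 12656 genes with at least 20 counts in 2 or more libraries, the length implied by count and FPKM was whole within 0.01 in 100% of genes and the same in each library. FPKM therefore carried no information beyond the counts. The submitters' processing notes name the builds GRCm38, mm10 and hg38 without saying which step used which. The aligner, the counting program and the strand setting are not given in the sources used here, and no coordinates are printed. No count row lacked a gene name. Of 22599 gene symbols, 21966 (97.2%) had a row in a RefSeq table of assembly GRCm38.p6, which served for names, for Entrez identifiers and for which genes neighbour Ncor1.

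Total counts ran from 36975231 to 38470468 per library. Genes were kept with edgeR's filterByExpr on group (minimum count 10, minimum total 15), which left 13205 genes holding 99.95% of the counts. TMM factors were computed, and NcoR1ΔHep was compared with flox by edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The replicate number was not a term, because the labels do not say that a number marks a litter or a day. Fold changes are log2 of NcoR1ΔHep over flox, with standard errors from the F statistic. Per-gene levels are the authors' FPKM as mean ± SD of 3 libraries. The labels do not say that each library came from a separate mouse, so p-values measure the spread between these libraries.

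Before the data were examined, 41 gene lists were fixed. They covered liver processes, sex-biased genes and markers of the cell types a liver sample can hold. Lists with at least 3 tested members (40) were tested with camera (limma 3.58.1) at its preset correlation of 0.01, adjusted over lists. Camera with an estimated correlation and fry were run beside it. Of the exocrine pancreas markers, 2 were tested, and their values are given instead. Mouse Reactome sets shipped with fgsea 1.28.0 and holding 10 to 300 tested genes (835 sets) were tested in the same way. The share of changed genes within 10 Mb of Ncor1 was compared with all other tested genes by Fisher's exact test, two-sided. Libraries were compared by Pearson correlation and principal components of log2(CPM + 1). For the level of Ncor1, an exact permutation test of the 6 FPKM values was added.

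The genes to be named were set by a rule fixed at the same time. It took Ncor1, then genes past the threshold, or the 10 genes with the smallest p if none passed. It added the 2 members of each list with the smallest p, and all genes of the sex-chromosome list. A gene named outside this rule is said to have been chosen after its values were seen.

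The gene and list tests were tried on simulated data. Independent counts were simulated from the means and edgeR's trended dispersions of these libraries (13205 genes). In them edgeR recovered 11% of the genes changed 2-fold and 79% of those changed 4-fold. When counts of 200 real genes were thinned in 1 group of the real libraries, edgeR called 0% at 2-fold, 58.5% at 4-fold and 70.5% at 8-fold, and DESeq2 called 24.5%, 81.0% and 89.0%. In a simulated list of 30 genes raised 1.5-fold, camera gave an adjusted p of 4.61e-09 with the preset correlation and 0.0756 with an estimated one. The simulated genes were independent of each other, a setting that favours the preset correlation. In the real lists the estimated correlation was 0.08 for cholesterol synthesis and 0.84 for male-biased genes. The simulation therefore does not test the preset p-values of correlated lists.

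The alternatives tried were DESeq2 1.42.0, RLE and upper-quartile factors, no count filter, a filter of CPM at least 1 in 3 libraries, a robust fit, limma-voom, and the replicate number as a block. Limma on log2(FPKM + 1) was also run, with a filter of FPKM at least 0.5 in 3 libraries, with a pseudocount of 0.1, and without a filter. Each library was left out in turn. For genes near Ncor1, windows of 5 and 20 Mb, DESeq2 calls and a background of the same chromosome were tried. After the data were seen, 3 alternatives were added: unadjusted p for genes near Ncor1, and the mean level of the circadian clock or de novo lipogenesis list as a covariate for the cholesterol synthesis list.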

Results

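The series set out to compare livers with and without NcoR1 in hepatocytes around ischemia-reperfusion injury, with attention to NF-kB p65. NcoR1 is a corepressor that nuclear receptors recruit to silence their target genes. The 6 libraries analysed here carry a 0 h time in their titles and form 2 groups, flox (n = 3) and NcoR1ΔHep (n = 3). They held 36975231 to 38470468 counts each, and 16620 to 17770 genes had at least 1 count. Albumin transcripts (Alb) took 6.56% to 8.85% of the counts of a library and mitochondrially encoded genes 4.50% to 10.4%.

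Ncor1 was measured first, as a check of the labels. Its level was 7.07 ± 0.570 FPKM in flox and 5.63 ± 0.886 FPKM in NcoR1ΔHep (SD, n = 3 each), 20.3% lower. In FPKM, which is scaled by total counts only, every NcoR1ΔHep library lay below every flox library. The values were 5.34, 6.63 and 4.93 FPKM against 6.78, 6.70 and 7.72 FPKM. The TMM factors of the edgeR test (1.11 for flox 1, 1.01 for NcoR1ΔHep 2) put NcoR1ΔHep 2 above flox 1. The separation therefore depends on the scaling. The edgeR log2 fold change was -0.31 (SE 0.21, 95% interval -0.80 to 0.17, adjusted p = 0.931). An exact two-sided permutation test of the FPKM values gave p = 0.1, the smallest that 3 libraries against 3 can give. Gene totals cannot show the loss of single exons, and cells other than hepatocytes in the tissue keep the gene. With 79.7% of the flox level left and no call, the check did not establish the loss of Ncor1. It also cannot exclude wrong labels, so the genotypes rest on the labels alone. The 15 other corepressor genes tested had a median log2 fold change of 0.03.

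One NcoR1ΔHep library differed from the other 5 in its sex-linked transcripts. Xist, which is transcribed from the inactive X chromosome, had 17138 counts in NcoR1ΔHep 1 and 6 to 18 in the others. The 4 Y-linked genes Ddx3y, Uty, Kdm5d and Eif2s3y summed to 0.534 CPM there and to 113 to 271 CPM in the others. Ddx3y had 12 counts in NcoR1ΔHep 1 and at least 2008 in each of the others, and Uty had 0, which allows up to 3 counts. Kdm5d and Eif2s3y had 2 and 6 counts there. The labels give no sex.

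**Figure D1:**
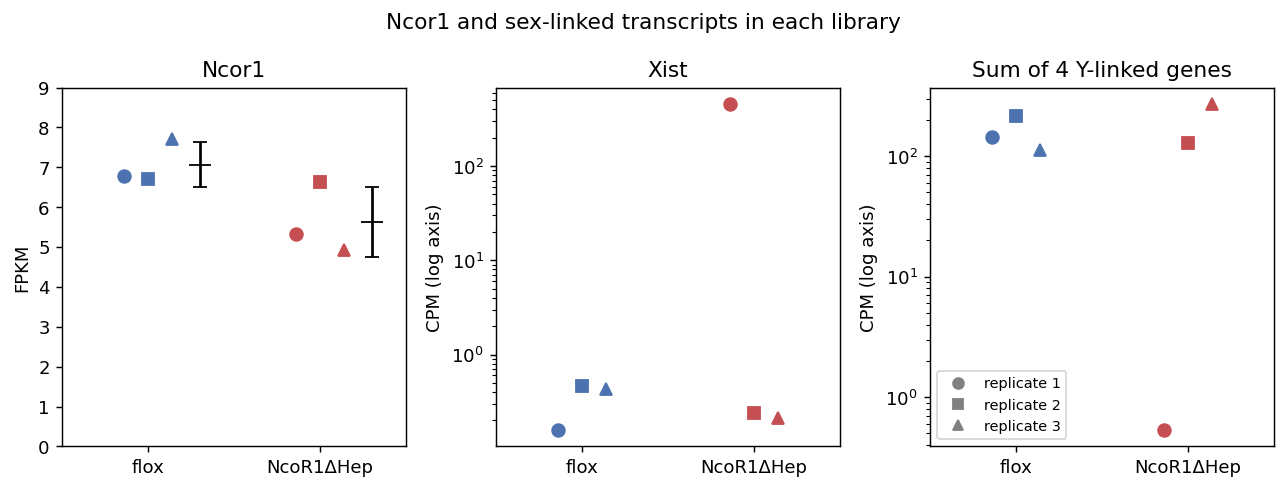
Levels per library of Ncor1 (FPKM, linear axis), Xist and the sum of 4 Y-linked genes (CPM, log axes), by genotype; each point is a library, its shape the replicate number, and the black marks beside Ncor1 show mean ± SD of 3 libraries. Ncor1 lay lower in every NcoR1ΔHep library in FPKM, but not with TMM factors. NcoR1ΔHep 1 had a Xist level of 457 CPM against at most 0.468 CPM elsewhere.

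The first question was which genes differed between the genotypes. No gene of 13205 passed the edgeR threshold (smallest adjusted p = 0.931), and 443 had an unadjusted p under 0.05, of which 189 were higher and 254 lower in NcoR1ΔHep. That is 3.35% of the tested genes, where chance gives 5%. DESeq2, run without the edgeR count filter (20289 genes with an adjusted p), called 5 genes, and 612 had an unadjusted DESeq2 p under 0.05. In independent counts simulated with edgeR's trended dispersion, 20 of 110 DESeq2 calls were false, against 5 of 95 edgeR calls. That simulation lacks the gene-specific spread of the real libraries and the correlation between genes. It therefore does not give the share of false calls among the 5 genes. The groups did not overlap in 998 genes (7.56%), where chance gives 10%. Of 200 genes thinned 2-fold in these libraries, edgeR called 0 and DESeq2 49 (24.5%).

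Of the 5 genes DESeq2 called, Lgr5 was higher and the other 4 were lower in NcoR1ΔHep. Lgr5, an R-spondin receptor and Wnt target of hepatocytes near the central vein, was at 0.554 ± 0.122 FPKM in flox and 1.40 ± 0.122 in NcoR1ΔHep, higher in 3 of 3 libraries (log2 fold change 1.37, SE 0.25; DESeq2 adjusted p = 0.00762, edgeR adjusted p = 0.931). Cdkn1a, the cell-cycle inhibitor p21, was at 4.74 ± 2.74 FPKM in flox and 1.08 ± 0.250 in NcoR1ΔHep (log2 fold change -2.08, SE 0.43; DESeq2 adjusted p = 0.0226). Ago2, an Argonaute protein of RNA silencing, had a log2 fold change of -1.98 (SE 0.39; DESeq2 adjusted p = 0.0226). Arntl, which encodes the clock activator BMAL1, had -3.23 (SE 0.84; DESeq2 adjusted p = 0.0317), with overlap between the groups. Srp54b had -3.46 (SE 0.66; DESeq2 adjusted p = 0.00686), but it shares reads with near-identical Srp54 copies, so its level is uncertain. The 4 lower genes fell in the same order within flox. In flox 1, flox 2 and flox 3, Cdkn1a was at 7.61, 4.46 and 2.15 FPKM and Ago2 at 1.21, 0.744 and 0.431. Arntl was at 1.29, 0.702 and 0.0983 FPKM there, and Srp54b at 0.962, 0.633 and 0.206. They therefore need not be 4 separate differences between the genotypes.

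The remaining genes among the 10 smallest edgeR p-values were lower in all 3 NcoR1ΔHep libraries than in every flox library, without passing either test. Rnf144b was at 11.6 ± 2.18 FPKM in flox and 5.81 ± 1.51 in NcoR1ΔHep, Ern1 at 9.85 ± 1.52 and 5.37 ± 0.124, and Crybg3 at 1.04 ± 0.159 and 0.545 ± 0.0228. Bmp10, a ligand of the BMP family, had a log2 fold change of -2.83 (SE 0.67) and the unnamed transcript 9230114K14Rik one of -2.62 (SE 0.67). Both rest on few reads. Bmp10 had 49, 14 and 15 counts in flox and 3, 4 and 3 in NcoR1ΔHep, and 9230114K14Rik 33, 35 and 11 against 3, 3 and 6. Zbed6 had -1.17 (SE 0.27), and lies within an intron of Zc3h11a, so its counts are uncertain.

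**Figure D2:**
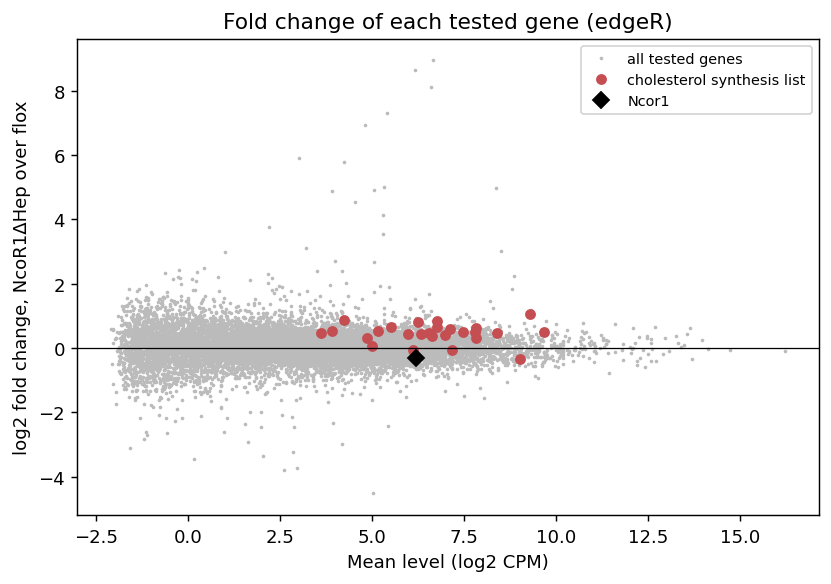
Fold change (log2, NcoR1ΔHep over flox) against mean level (log2 CPM) for the 13205 tested genes, in grey, with the cholesterol synthesis list in red and Ncor1 as a black diamond. The median of all genes was 0.03, and 23 of the 26 cholesterol genes lay above 0.

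Genes of cholesterol synthesis were higher in NcoR1ΔHep as a group. Of 26 measured genes, 23 were higher and 7 of these had an unadjusted p under 0.05, none with an adjusted p under 0.05 over all genes or adjusted over the list alone. The median log2 fold change was 0.48 (quartiles 0.38 and 0.61), and the mean level of the list was higher in each NcoR1ΔHep library than in each flox library. Chance separates 3 libraries from 3 in 10% of cases. Among all the lists, only this one and the endoplasmic reticulum stress list separated, so such separation was no more frequent than chance gives. Sqle, the squalene epoxidase, was at 20.3 ± 6.56 FPKM in flox and 35.3 ± 5.85 in NcoR1ΔHep (log2 fold change 0.81, SE 0.26). Lss, the lanosterol synthase that follows it, was at 5.25 ± 1.21 and 8.09 ± 2.05 (0.64, SE 0.23). Hmgcs1, chosen after its values were seen, had a log2 fold change of 1.06 (SE 0.38). Camera gave the list an adjusted p = 5.32e-09 with the preset correlation and an adjusted p = 0.542 with an estimated correlation. By fry the adjusted p was 0.319.

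Of 26 de novo lipogenesis genes, 19 were higher, with a median log2 fold change of 0.21, but no member had an unadjusted p under 0.05. The mean level of the list was low in flox 1, flox 2 and NcoR1ΔHep 3 (-0.27, -0.46 and -0.27 log2 CPM from the mean of the 6 libraries) and high in flox 3, NcoR1ΔHep 1 and NcoR1ΔHep 2 (0.27, 0.43 and 0.31), a division that crosses the genotypes. Acss2, which makes acetyl-CoA from acetate, was at 72.5 ± 6.99 FPKM in flox and 110 ± 43.6 in NcoR1ΔHep, and Pnpla3 had a log2 fold change of 2.38 (SE 1.23) that was 0.35 without NcoR1ΔHep 1. Camera gave an adjusted p = 0.0316 with the preset correlation and an adjusted p = 0.768 with an estimated correlation. The preset call ended without flox 1, flox 2, NcoR1ΔHep 1 or NcoR1ΔHep 2 (medians 0.14, 0.14, 0.21 and 0.09; adjusted p = 0.0691, 0.324, 0.195 and 0.393) and with limma on unfiltered FPKM (0.22, adjusted p = 0.109). Without flox 3 or NcoR1ΔHep 3 the median was 0.40 or 0.38.

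Targets of the nuclear receptors that NcoR1 can repress did not pass as lists. LXR targets had 10 of 18 genes higher, a median log2 fold change of 0.13 and a camera adjusted p = 0.288. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, was at 10.8 ± 9.31 FPKM in flox and 27.4 ± 5.87 in NcoR1ΔHep (1.32, SE 0.57), and Pltp had 1.27 (SE 0.55), or 0.28 without NcoR1ΔHep 1. Cyp7a1 was at 4.09, 6.97 and 21.5 FPKM in flox 1, flox 2 and flox 3, and at 20.6 to 31.3 FPKM in NcoR1ΔHep. Thyroid hormone targets had 11 of 20 higher (median 0.08, camera adjusted p = 0.554), with Tat at 238 ± 46.4 and 392 ± 57.6 FPKM and Gadd45a at 4.07 ± 2.54 and 9.26 ± 2.96 FPKM. PPAR-alpha targets had 32 of 47 lower (median -0.15, camera adjusted p = 0.161). Within that list Etfdh had -0.73 (SE 0.33), and Acot3 had 4.53 (SE 1.49), with 35.8 FPKM in NcoR1ΔHep 1 and at most 4.83 FPKM elsewhere. Bile acid synthesis genes had a median of -0.13 (camera adjusted p = 0.445), and transporters of the FXR axis one of -0.17 (camera adjusted p = 0.212). Without NcoR1ΔHep 1 these medians were -0.01 and 0.07, and those of LXR, thyroid hormone and PPAR-alpha targets were 0.05, 0.15 and -0.13, of which the last passed with the preset correlation (adjusted p = 0.0423). Among the transporters, Abcc2 was at 52.3 ± 14.0 FPKM in flox and 28.9 ± 3.07 in NcoR1ΔHep, and Abcb11, the bile salt export pump, at 122 ± 6.20 and 84.4 ± 12.8. Neither passed the adjusted threshold (edgeR adjusted p = 0.931 for both).

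Endoplasmic reticulum stress genes were lower in NcoR1ΔHep, with 19 of 28 lower and a median log2 fold change of -0.27. Ern1, which encodes the stress sensor IRE1, had -0.85 (SE 0.21), and the chaperone gene Hyou1 was at 37.9 ± 17.9 FPKM in flox and 19.7 ± 7.43 in NcoR1ΔHep. Hyou1 was at 58.2, 24.5 and 31.0 FPKM in flox 1, flox 2 and flox 3 and at 28.1 FPKM in NcoR1ΔHep 2, so the groups overlapped. The mean level of the list was lower in each NcoR1ΔHep library than in each flox library, which chance gives, in either direction, in 10% of cases. The margin was narrow, with 0.031 in flox 2 and -0.0014 in NcoR1ΔHep 2 (log2 CPM from the mean of the 6 libraries). These levels use TMM factors (0.933 for flox 2, 1.01 for NcoR1ΔHep 2). Whether the separation holds with scaling by total counts only was not tested. Camera gave an adjusted p = 0.00556 with the preset correlation and an adjusted p = 0.768 with an estimated correlation. Without flox 1, which had the highest level, the median was -0.13 and the preset adjusted p = 0.0240. Apoptosis, necroptosis and pyroptosis genes had 20 of 39 higher and a median of 0.02 (camera adjusted p = 0.655; median 0.07 without NcoR1ΔHep 1). In that list Cdkn1a alone passed when adjusted over the list alone (edgeR adjusted p = 0.0481, against 0.931 over all genes). Adjusting within each list does not correct for the number of lists. In all, 2 members passed in this way, Cdkn1a and Lgr5, and a few such passes can arise by chance. Bmf had 0.98 (SE 0.32). Bmf was at 2.62 FPKM in NcoR1ΔHep 1, at 1.37 and 1.10 FPKM in NcoR1ΔHep 2 and NcoR1ΔHep 3, and at 0.698 to 0.958 FPKM in flox.

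Targets of NF-kB, the pathway named by the series, did not pass as a list. Of 31 measured targets 17 were higher and 14 lower, the median log2 fold change was 0.00 (quartiles -0.25 and 0.32), and camera gave an adjusted p = 0.978. Nfkb1 itself had -0.44 (SE 0.22) and Irf1 had 0.50 (SE 0.28). Irf1 was at 4.81 ± 1.03 FPKM in flox and at 10.1 FPKM in NcoR1ΔHep 1. In NcoR1ΔHep 2 and NcoR1ΔHep 3 it was at 4.74 and 5.45 FPKM. Chemokines and cytokines (median 0.07, camera adjusted p = 0.679) and interferon-stimulated genes (0.03, adjusted p = 0.978) did not pass. Among them Il18 was at 3.96 ± 0.256 FPKM in flox and 6.14 ± 1.86 in NcoR1ΔHep, and Ccl6 at 11.6 ± 2.71 and 7.74 ± 1.88. Il18 was at 8.27 FPKM in NcoR1ΔHep 1, and at 4.83 and 5.32 FPKM in NcoR1ΔHep 2 and NcoR1ΔHep 3. Psmb9 had 0.65 (SE 0.28), or 0.36 without NcoR1ΔHep 1. Gbp2 had -0.72 (SE 0.34), with 4.13 FPKM in flox 1 and 1.39 to 1.82 FPKM in the other libraries. Acute-phase proteins had 22 of 31 lower with a median of -0.16 but a mean of 0.06, and camera gave an adjusted p = 0.560. Without NcoR1ΔHep 1 the medians had the other sign for NF-kB targets (-0.04), chemokines (-0.04) and acute-phase proteins (0.07). In that list Orm3 had 2.19 (SE 0.94) and the metallothionein Mt1 had 1.92 (SE 0.90), against 0.07 and 0.61 without NcoR1ΔHep 1. The level of this list differed between libraries of the same genotype: Saa1, chosen after its values were seen, was at 2497 CPM in flox 3 and 2152 CPM in NcoR1ΔHep 2, against 21.3 to 133 CPM in the other 4.

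Immediate early genes had 23 of 30 higher, with a median log2 fold change of 0.60. The mean level of the list divided the libraries as lipogenesis did, with -0.44, -1.07 and -0.45 in flox 1, flox 2 and NcoR1ΔHep 3 and 0.66, 0.45 and 0.85 in flox 3, NcoR1ΔHep 1 and NcoR1ΔHep 2. Sik1 was at 1.68 ± 1.32 FPKM in flox and 4.53 ± 1.36 in NcoR1ΔHep, and Dusp6 at 15.7 ± 6.75 and 24.6 ± 5.07. The list had an adjusted p = 0.000132 with the preset correlation and an adjusted p = 0.768 with an estimated correlation. The preset call ended without flox 2 (median 0.25, adjusted p = 0.199) or NcoR1ΔHep 2 (0.13, adjusted p = 0.233). The median was 1.08 without flox 3 and 0.35 with limma on unfiltered FPKM. Heat shock genes (median -0.17, camera adjusted p = 0.212; -0.10 without NcoR1ΔHep 1) and hypoxia genes (-0.09, adjusted p = 0.478; 0.02 without NcoR1ΔHep 1) did not pass. Their leading members were Hsph1 with -0.78 (SE 0.30) and Ndrg1 with -1.48 (SE 0.51). Ndrg1 was at 17.9, 7.78 and 3.19 FPKM in flox 1, flox 2 and flox 3, and at 2.19 to 3.94 FPKM in NcoR1ΔHep.

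Of 26 genes of hepatocytes near the central vein, 21 were higher, with a median of 0.32. The mean level of the list was high in NcoR1ΔHep 1 and NcoR1ΔHep 3 (0.50 and 0.36 log2 CPM from the mean of the 6 libraries), but in NcoR1ΔHep 2 (-0.34) it lay below every flox library (-0.29, -0.02 and -0.21). Lgr5 passed when adjusted over the list alone (edgeR adjusted p = 0.0145, against 0.931 over all genes), with no correction for the number of lists. Znrf3, another Wnt feedback gene, was at 0.698 ± 0.133 FPKM in flox and 1.22 ± 0.165 in NcoR1ΔHep. For this list camera gave an adjusted p = 0.00167 with the preset correlation and an adjusted p = 0.768 with an estimated correlation. The preset call ended without NcoR1ΔHep 1 (median 0.11, adjusted p = 0.0704) or NcoR1ΔHep 3 (0.29, adjusted p = 0.0929). The median was 0.19 without flox 1, 0.51 without NcoR1ΔHep 2 and 0.19 with limma on log2(FPKM + 1). Periportal genes had 17 of 24 lower and a median of -0.09 (camera adjusted p = 0.374, median 0.00 without NcoR1ΔHep 1). Apoa4 had -1.05 (SE 0.46), set by flox 1, with 673 FPKM there and 141 to 196 FPKM in the other libraries.

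Circadian clock genes had 15 of 19 higher, with a median of 0.38. Besides Arntl, the member with the smallest p was Nfil3, a repressor in the same loop, at 6.29 ± 3.38 FPKM in flox and 2.98 ± 1.71 in NcoR1ΔHep, which overlapped and passed neither test. The clock list had a camera adjusted p = 0.00839 with the preset correlation and an adjusted p = 0.768 with an estimated correlation. The preset call ended without flox 1, NcoR1ΔHep 1 or NcoR1ΔHep 3 (medians 0.31, 0.42 and 0.24; adjusted p = 0.0517, 0.0704 and 0.204) and with DESeq2 (0.39, adjusted p = 0.415). Without flox 3 or NcoR1ΔHep 2 the median was 0.74 or 0.59. The difference came with 2 flox libraries: Dbp, chosen after its values were seen, was at 0.948 and 3.76 FPKM in flox 1 and flox 2, and at 37.6 to 92.6 FPKM in the other 4 libraries.

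Among cell type markers, those of liver sinusoidal endothelial cells were lower in NcoR1ΔHep in 19 of 21 genes, with a median log2 fold change of -0.60. The mean level of that list was 0.85, -0.13 and 0.12 in flox and 0.16, -0.45 and -0.56 in NcoR1ΔHep, so the groups overlapped. F8, the coagulation factor VIII gene, was at 1.40 ± 0.759 FPKM in flox and 0.669 ± 0.102 in NcoR1ΔHep, and the endothelial phosphatase gene Ptprb at 4.72 ± 2.20 and 2.42 ± 0.625. Camera gave an adjusted p = 1.87e-08 with the preset correlation and an adjusted p = 0.768 with an estimated correlation. Flox 1 had the highest level, and without it the median was -0.27 (preset adjusted p = 0.000927); without NcoR1ΔHep 1 it was -0.91 (1.73e-16). Kupffer cell markers were lower in 15 of 18 genes (median -0.26), with Cd68 at 10.9 ± 2.74 and 6.96 ± 2.10 FPKM. Camera gave them an adjusted p = 0.00801 with the preset correlation and an adjusted p = 0.768 with an estimated correlation, and the preset call ended without flox 3 (median -0.09, adjusted p = 0.201) or NcoR1ΔHep 3 (-0.07, 0.506). Without NcoR1ΔHep 2 the median was -0.52. The mean level of the Kupffer list was 0.22, -0.11 and 0.35 in flox and -0.20, 0.28 and -0.54 in NcoR1ΔHep, again with overlap.

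Apart from the pericentral, endothelial and Kupffer cell lists, no cell type list passed camera with the preset correlation (smallest adjusted p = 0.106, for adipocytes). The medians were 0.03 for monocytes and infiltrating macrophages, -0.27 for neutrophils, 0.05 for T and NK cells, 0.25 for B and plasma cells and 0.18 for dendritic cells. They were 0.07 for stellate cells and fibroblasts, 0.23 for cholangiocytes, -0.22 for erythroid cells and -0.60 for adipocytes. Without NcoR1ΔHep 1, the Xist-positive library, the medians had the other sign for monocytes (-0.17), neutrophils (0.04), T and NK cells (-0.39), B and plasma cells (-0.20) and dendritic cells (-0.26), and were 0.15 for stellate cells and -0.10 for erythroid cells. Chil3 was at 8.23 ± 3.15 FPKM in flox and 4.67 ± 1.36 in NcoR1ΔHep, Epcam at 0.356 ± 0.123 and 0.835 ± 0.432, and Ecm1 at 30.2 ± 9.34 and 62.1 ± 46.1 (log2 fold change 0.34 without NcoR1ΔHep 1). The adipocyte genes Cidec and Fabp4 were high in flox 1, with 20.5 and 20.4 FPKM against at most 3.22 and 10.8 in the others. The pancreatic elastase genes Cela1 and Cela2a had log2 fold changes of -0.09 (SE 0.28) and 0.53 (SE 0.71).

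**Figure D3:**
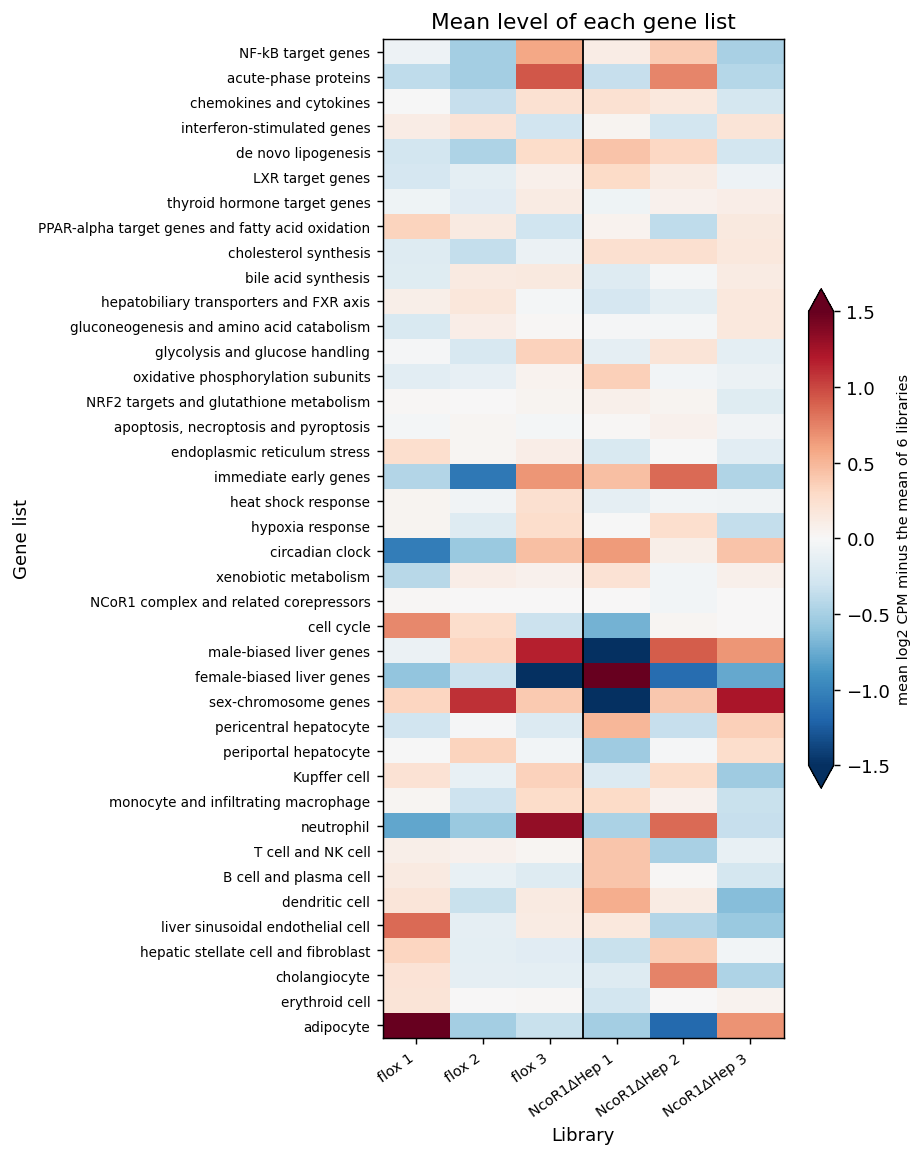
Mean level of 40 gene lists in each library, as mean log2 CPM of the members minus their mean over the 6 libraries (colour scale held at ± 1.5), with the line parting flox from NcoR1ΔHep. The cholesterol synthesis list is higher and the endoplasmic reticulum stress list lower in every NcoR1ΔHep library, the sex-biased lists are set by NcoR1ΔHep 1, and the acute-phase list is high in flox 3 and NcoR1ΔHep 2. The endoplasmic reticulum stress list separates by a narrow margin (0.031 in flox 2, -0.0014 in NcoR1ΔHep 2). No other list separates the genotypes, and chance separates 3 libraries from 3 in 10% of cases.

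The sex-biased lists followed NcoR1ΔHep 1. Female-biased liver genes had a median log2 fold change of 3.61 over 22 genes (camera adjusted p = 6.52e-08 with the preset correlation, 0.768 with an estimated correlation as adjusted p), and 0.11 without that library (preset adjusted p = 0.973). With that library kept, the CPM filter, limma-voom, the replicate block and limma on FPKM gave lower medians, from 2.32 (CPM filter) to 1.11 (log2(FPKM + 1)). Sult2a1, a sulfotransferase gene, was at 0.405 ± 0.0757 FPKM in flox and 212 ± 366 in NcoR1ΔHep, an SD that exceeded the mean, and Slc22a26 at 1.09 ± 0.404 and 20.2 ± 32.0. Male-biased genes had a median of -0.34 over 24 genes (preset adjusted p = 0.00135, estimated-correlation adjusted p = 0.785). Without NcoR1ΔHep 1 the median was 0.16 (preset adjusted p = 0.0502), and without flox 3 it was 0.02 (0.374); it was -0.54, -0.86 and -0.63 without flox 1, NcoR1ΔHep 2 and NcoR1ΔHep 3. The call also ended with DESeq2 (-0.31, adjusted p = 0.173), and the median was -0.83 with limma-voom, -0.80 with the replicate block and -0.74 with limma on log2(FPKM + 1). Elovl3, a fatty acid elongase gene, was at 94.2 ± 44.0 and 35.8 ± 37.5 FPKM. Xenobiotic metabolism genes did not pass (median 0.17, camera adjusted p = 0.288; median 0.10 without NcoR1ΔHep 1), and Cyp2a4 in that list was at 11.7 ± 9.19 and 399 ± 664 FPKM, again set by NcoR1ΔHep 1.

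Oxidative phosphorylation subunits had 45 of 54 genes higher at a median of 0.19, with Atp5j at 41.1 ± 5.09 FPKM in flox and 59.7 ± 19.8 in NcoR1ΔHep and Sdha lower at 196 ± 33.0 and 130 ± 31.2. Camera gave an adjusted p = 0.0117 with the preset correlation and an adjusted p = 0.807 with an estimated correlation. The preset call ended without NcoR1ΔHep 1 (median 0.03, adjusted p = 0.746), flox 1 (0.15, adjusted p = 0.0691) or flox 2 (0.15, adjusted p = 0.0901), and the median was 0.30 without NcoR1ΔHep 2. Libraries also differed in how their levels followed gene length: the Spearman correlation across genes, which are not independent replicates, was 0.24, 0.22 and -0.14 in the flox libraries and -0.20, -0.17 and 0.09 in the NcoR1ΔHep libraries. Cell cycle genes had 27 of 36 lower at a median of -0.56, with Bub1 at 0.133 ± 0.0505 and 0.0287 ± 0.0233 FPKM. Camera gave them an adjusted p = 0.000709 with the preset correlation and an adjusted p = 0.768 with an estimated correlation, and the preset call ended without flox 1 (median -0.13, adjusted p = 0.0988) or NcoR1ΔHep 1 (-0.37, adjusted p = 0.240). It also ended with the CPM filter (-0.11, adjusted p = 0.0890) and with limma on log2(FPKM + 1) (-0.08, 0.4005) or log2(FPKM + 0.1) (-0.10, 0.452), and the median was -0.12 on unfiltered FPKM, where the call held.

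Lists of intermediary metabolism did not pass. Gluconeogenesis and amino acid catabolism had a median of 0.12 (camera adjusted p = 0.478), glycolysis -0.06 (0.312) and NRF2 targets with glutathione metabolism 0.04 (0.978). Without NcoR1ΔHep 1 the medians were 0.11, -0.02 and 0.10. In the last list Osgin1 was at 98.5 ± 49.8 FPKM in flox and 44.2 ± 7.46 in NcoR1ΔHep. The flox mean of Osgin1 was raised by flox 1, with 156 FPKM there and 73.4 and 66.4 FPKM in flox 2 and flox 3. Gsta1 had -2.70 (SE 0.71), uncertain because Gsta2 is nearly identical. In all, 12 of 40 lists passed camera with the preset correlation, 7 higher and 5 lower, and none passed with an estimated correlation or by fry. Without NcoR1ΔHep 1, 7 lists passed with the preset correlation, 5 of them among the 12; the other 2, lower in NcoR1ΔHep, were PPAR-alpha targets (adjusted p = 0.0423) and T and NK cell markers (0.0326).

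Of 835 Reactome sets, 18 passed with the preset correlation, all higher in NcoR1ΔHep. Cholesterol biosynthesis ranked first (22 genes, median log2 fold change 0.50, adjusted p = 9.9e-07; estimated-correlation adjusted p = 0.839). The SREBF activation set also passed (23 genes, 0.31, adjusted p = 0.00335; estimated-correlation adjusted p = 0.839), and most of the others held ribosomal protein or respiratory chain genes. No set passed with an estimated correlation. Without NcoR1ΔHep 1, 3 sets passed, 2 of them among the 18, cholesterol biosynthesis (adjusted p = 3.71e-07) and SREBF activation (0.0297). The count was 5 without flox 1, 39 without flox 3, 28 without NcoR1ΔHep 2 and 36 without NcoR1ΔHep 3.

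Genes linked to a targeted allele can differ between strains, so the neighbours of Ncor1 were examined. Per the labels the flox group also carried floxed Ncor1 alleles, so linked sequence need not have differed between the groups. The comparison is therefore a weak check of linked alleles. Of 228 tested genes within 10 Mb, 0 passed the edgeR threshold, as did 0 of the 12921 others. With 0 genes past the threshold in all, that comparison could not have come out otherwise. With an unadjusted edgeR p under 0.05, 5 neighbours (2.19%) stood against 435 others (3.37%; Fisher's exact test, two-sided, p = 0.455).

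Libraries of the same genotype were no more alike than libraries of different genotypes. The mean Pearson correlation of log2(CPM + 1) was 0.966 within groups and 0.967 between groups. The closest pairs crossed the genotypes, flox 3 with NcoR1ΔHep 2 (r = 0.992) and flox 2 with NcoR1ΔHep 3 (r = 0.988), over genes, which are not independent replicates. NcoR1ΔHep 1 stood apart, with a mean r of 0.946 to the other 5, and lay at the end of the first principal component, which held 47.1% of the variance.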

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

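The settings were listed before the data were examined, except the unadjusted threshold for genes near Ncor1 and the 2 covariates for the cholesterol synthesis list. DESeq2 called 5 genes where edgeR called 0, a change of gene set as well as of test, because DESeq2 ran without the count filter. EdgeR under the other factors, filters, robust fit and fold threshold, limma-voom, and limma on FPKM called 0, as did edgeR with each library left out. Genes with an unadjusted p under 0.05 numbered 443, and 691 with no count filter, which tests more genes. Leaving out a library gave 105 (without flox 1) to 932 (without NcoR1ΔHep 3), and 743 and 770 without flox 3 or NcoR1ΔHep 2. The cause was not tested. The fold change of Ncor1 stayed negative and short of the threshold under all alternatives, from -0.43 to -0.21 with a library left out. Lists past the threshold went from 12 to 0 with an estimated correlation and to 0 by fry, and ranged from 7 (without NcoR1ΔHep 1) to 16 with a library left out. Reactome sets went from 18 to 0 with an estimated correlation and ranged from 3 to 39 with a library left out. Under the other gene-level settings, 126 of 132 values of the 12 lists stayed past the threshold in the same direction. With a library left out, 51 of 72 did. Genes near Ncor1 numbered 0 in each window and on the same chromosome, where edgeR called 0 genes in all. They numbered 0 by DESeq2, and 5 at an unadjusted edgeR p under 0.05. The similarity of libraries kept its sign on log2(FPKM + 1). With the replicate number as a block, edgeR called 0 genes, and 175 had an unadjusted p under 0.05. Same-numbered libraries had correlations of deviations of 0.02, -0.33 and -0.47. These values show no pairing by number, but so few pairs cannot exclude a small shared effect of litter or day. Of 1483 alternative values of the 90 named genes, 1464 kept direction and side, 5 passed under DESeq2 and 14 changed sign, all with a library left out and none past the threshold. Without NcoR1ΔHep 1 the sign changed for Xist (-0.56; range -0.56 to 9.21), Ddx3y (0.55; -1.45 to 0.55), Uty (0.51; -0.99 to 0.51), Kdm5d (0.30; -1.19 to 0.30), Eif2s3y (0.26; -1.26 to 0.26), H2-Eb1 (-0.032; -0.032 to 0.96), H2-Aa (-0.16; -0.16 to 0.99) and Cela1 (0.06; -0.25 to 0.20). It changed for Ddx3y (0.50) and Uty (0.34) without flox 2, Ddx3y (0.11) and Cela2a (-0.10; -0.10 to 1.10) without NcoR1ΔHep 2, Cidec (1.56; -3.94 to 1.56) without flox 1 and Cela1 without flox 3. The male-biased list had 0.16 without NcoR1ΔHep 1 and 0.02 without flox 3 (range -0.86 to 0.16). For Xist and the Y-linked genes, the changes without NcoR1ΔHep 1 follow from the counts of that library, 17138 for Xist and 0 to 12 for the Y-linked genes. The causes of the other changes were not tested.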

Other observations

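The tests of the sex-linked library and of its effect on the count of calls and on the cholesterol list were chosen after the values were seen. The other splits of the libraries and the covariates for clock and feeding were set before their results were seen. Cidea, Cfd, Egr1, Cxcl1, Dbp, Per2, S100a8 and S100a9 were chosen after their values were seen.

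Several genes had levels that ranged widely between libraries of the same genotype. Cidea, a lipid-droplet protein gene abundant in brown fat and fatty liver, was at 179 FPKM in flox 1 and at most 6.24 FPKM in the other 5 libraries, and Cfd, an adipocyte gene, at 114 against at most 11.5. Egr1, an immediate early gene, ranged from 12.0 FPKM in NcoR1ΔHep 3 to 184 in NcoR1ΔHep 2, and Cxcl1, a neutrophil chemokine, from 2.20 in flox 2 to 54.3 in NcoR1ΔHep 2. Arntl was at 1.29 and 0.702 FPKM in flox 1 and flox 2, and at most 0.109 in the other 4 libraries, where Dbp and Per2 were higher. Acute-phase and neutrophil genes were high in the same 2 libraries: the mean level of the acute-phase list was 0.93 in flox 3 and 0.73 in NcoR1ΔHep 2 (log2 CPM minus the mean of the 6 libraries) and at most -0.34 in the other 4, and that of the neutrophil list 1.31 and 0.85 against at most -0.35. S100a8 was at 11.2 and 5.47 FPKM in these 2 libraries and at 1.28 to 4.37 in the others, and S100a9 at 9.50 and 5.63 against 1.44 to 3.02.

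Other splits of the 6 libraries into 3 and 3 make 10 in all, too few for a share under 0.05. The genotype split called 0 genes by edgeR, so that all 10 splits reached its count by construction, and the highest other called 5. That split, flox 1, flox 2 and NcoR1ΔHep 3 against the rest, had 2968 genes with an unadjusted p under 0.05 against 443 for the genotypes, which points to a structure of the samples that crosses the genotypes. The Spearman correlation of level with gene length, across genes, which are not independent replicates, divided the libraries in the same way: 0.24, 0.22 and 0.09 against -0.14, -0.20 and -0.17. The cause of this structure was not tested. For lists with the preset correlation, 6 of the 10 splits gave as many as the 12 of the genotype split, and the highest other gave 17. For Reactome sets, 8 of the 10 gave as many as the 18, and the highest other gave 74.

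The first pattern is the library NcoR1ΔHep 1, with Xist and almost no Y-linked reads. Its Y-linked transcripts summed to 0.306% of the mean of the other 5, which argues against RNA of both sexes in the library. A female animal is a candidate explanation: 93.5% of the 46 tested sex-biased genes (43) were most extreme in this library in the female direction, where chance gives 16.7%. Its Ncor1 level (5.34 FPKM) lay below every flox library (6.70 to 7.72), as its label says, but 1 library in a gene that did not pass decides little, and a wrong label or a swap stays open. Without this library the common dispersion went from 0.127 to 0.0958 and 0 genes passed the edgeR threshold (325 with an unadjusted p under 0.05), so whether it hid differences between genotypes cannot be told apart from the loss of a replicate.

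The second pattern is the higher level of cholesterol synthesis genes in NcoR1ΔHep. It did not rest on the Xist-positive library: without it 25 of 26 genes were higher, the median was 0.47 (SD over members 0.23) and the preset camera adjusted p was 1.66e-10. With the clock list as a covariate the median was 0.40 (SE 0.07) and the preset camera adjusted p = 1.41e-07. With the lipogenesis list, a stand-in for feeding, they were 0.38 (SE 0.07) and 2.34e-06, against 0.48 and 5.32e-09 with neither. Camera with an estimated correlation gave an adjusted p of 0.635 and 0.533. The list thus stayed higher with either covariate. The SEs are over members, which are not independent replicates, and the clock list mixes genes that moved in opposite directions. These fits therefore do not decide whether clock or feeding contributed. The genotype split gave the smallest camera p of the 10 splits (1 of 10, 1.33e-10, smallest other 0.00332), a number of splits that cannot reach a share under 0.05. The list also had the smallest camera p of the 40 lists under the genotype split, which favours that split in this ranking. An effect of NcoR1 loss on this pathway remains open as a hypothesis, as do clock, feeding, litter, cage and day, which the labels do not give.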
